A study of Mus musculus with 58 samples.

How the data were processed

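Bone marrow cells of C57BL/6 mice were sorted singly by surface markers and their RNA was reverse transcribed by a modified Smart-seq2 protocol, per the labels' protocols. The oligo(dT) primer carried a cell barcode and a molecular identifier, cDNA of barcoded cells was pooled, and 3' ends were captured for sequencing. The submitters' processing notes name the mouse build mm10 and the tools TopHat2 2.0.12, HTSeq and Seurat 2.0, with no role or order. The authors deposited 1 table of whole-number counts, with a gene symbol in each row and a cell in each column. Whether these counts are molecules or reads was not stated in the sources used here. They are treated as counts, and every interval covers counting error only. Amplification would make the true error larger.

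Each deposited column was matched to a cell by its name, and each cell to a gate by its title. All 58 columns were used, 34 of LT-HSC and 24 of CMP. No cell was removed, no gene was filtered before totals were taken, and no doublet caller was run on these singly sorted cells. Of 23152 symbols, 10265 had no count in any cell. These include genes that every cell uses, such as the glycolysis gene Eno1, so a gene without a count in any cell may have been lost in mapping or counting. Rn45s, a ribosomal RNA precursor, took 1.66% of the LT-HSC and 1.71% of the CMP counts.

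Counts were summed over the cells of a gate and divided by the summed total to give CPM, the count scaled to a common total, with exact Poisson 95% intervals. The log2 ratio of LT-HSC to CMP used 0.5 added to each count, and its interval came from the exact conditional binomial distribution. A pool without a count was set to a floor of 3 counts over the pool (0.30 CPM in LT-HSC and 0.42 in CMP), and the fold against it was given as a lower bound. Setting such members to the floor left the pooled median of each of the 15 lists as printed. Shares of cells carry exact Clopper-Pearson intervals. Cells are not replicates, so no p-value, standard error or count of changed genes was computed.

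Gene lists and marker sets were fixed before the data were examined. They covered stem cell, granulocyte and monocyte, erythroid, megakaryocyte, lymphoid, S phase, G2 and M phase, cell cycle restraint, immediate early and stress, ribosome biogenesis, ribosomal protein, glycolysis, oxidative phosphorylation, interferon response and MHC genes, the gate genes, sex-linked genes and mitochondrially encoded genes. Marker sets covered mature erythroid, B, T or NK, neutrophil, macrophage, basophil, mast or eosinophil, dendritic, endothelial and stromal cells. A list's value is the median log2 ratio of members with at least 20 counts over both pools. Its percentile is its place among 10000 random lists of the same size matched on mean CPM in 20 bins, and it describes these 2 pools only. Some genes belong to more than 1 list, such as Vwf and Slamf1, which the stem cell and megakaryocyte lists share.

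The genes named were also chosen by a rule fixed before the data were examined. From genes with at least 50 counts, a count in at least 1 of every 3 cells of the higher pool, no cell with more of that pool's counts than all its other cells together and the same direction by pooled and mean CPM, the 12 highest and 12 lowest log2 ratios were taken. Gate, sex-linked, mitochondrially encoded and ribosomal protein genes and predicted models stayed out. To these were added up to 4 members per list with the largest log2 ratios, all gate and sex-linked genes, and Mpo, Elane, Gata1 and Klf1. Further list members named as examples, and Tnf, Nlrp3, Eno1, Rn45s, Wfdc17, Gkn3 and Slfn2, were chosen after their values were seen. Some list members and the markers of mature erythroid cells are not reported here. Coordinates are 1-based on mm10 from GENCODE M21.

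For comparisons of genes per cell and shares of cells, each cell was thinned at random without replacement to 97978 counts, the 10th percentile of totals, and shallower cells were left out. For clustering, counts were scaled to 10000 per cell and log2 transformed after adding 1. The 1000 genes with the largest variance for their mean, among those in at least 3 cells, were centred and scaled. The first 10 principal components entered Ward clustering, at 2 and 4 clusters. The first 2 components held 5.29% and 4.54% of the variance. No cluster was named as a cell type.

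Alternatives fixed beforehand were the mean of each cell's CPM, median-of-ratios scaling, a total without ribosomal protein genes, leaving out cells with less than 1 part in 3 of their gate's median total, thinning, an added count of 1, leaving out each cell in turn, other minimum counts for list members and detection, and other clustering settings. Restricting to cells without an Xist count, leaving out CMP 1 and 2, taking LT-HSC 1 to 16 or 17 to 34 only, a minimum of 10 counts for detection, unscaled genes in clustering and clustering without shallow cells were added after the data were seen. The ratio and list steps were tested on simulated data. Counts for 9931 genes were drawn from the mean shares and totals of both pools, with 200 genes changed by a log2 ratio of 2 in either direction. The median estimates were 2.00 and −2.00, 96.0% of the intervals of changed genes and 95.8% of those of unchanged genes held the true value, a list of changed genes reached percentile 100 and a list of unchanged genes percentile 7.96. This simulation holds no amplification noise and no variation between cells. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.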

Results

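The data were RNA counts of 58 single cells sorted from the bone marrow of C57BL/6 mice. Of these, 34 came from the gate for long-term haematopoietic stem cells (LT-HSC), which lack lineage markers, carry Kit and Sca-1 and lack Flt3 and CD34. The other 24 came from the gate for common myeloid progenitors (CMP), which carry Kit and CD34 and lack lineage markers, Sca-1 and CD16/32. The table listed 23152 gene symbols, of which 12887 had a count in at least 1 cell. An LT-HSC held a median of 236774 counts (range 45022 to 860553), and a CMP a median of 290977 (range 88329 to 706184). Summed over cells, the LT-HSC pool held 9931131 counts and the CMP pool 7062737. Because no label names an animal, each gate was 1 sample. No difference below has a replicate check, no test was made, and intervals are 95% intervals for counting error only. They are too narrow if the deposited counts are reads and not molecules, which was not stated in the sources used here.

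Transcripts of the gate genes were compared between the gates. The gates were set on surface markers, so RNA of these genes cannot show by itself whether the sort held. Ly6a, which encodes Sca-1, stood at 132 CPM in LT-HSC and 15.1 in CMP, 8.68-fold higher in LT-HSC. Without CMP cell 14 its log2 ratio moved from 3.11 to 3.77. Kit was at 128 CPM in LT-HSC and 186 in CMP. Fcgr3, 1 of the genes behind CD16/32, was low in both pools, at 0.81 CPM in LT-HSC and 17.0 in CMP, and Fcgr2b stood at 2.42 and 14.9. Without LT-HSC 17 the log2 ratio of Fcgr2b moved from −2.60 to −3.35, and with only the cells without an Xist count, where the CMP held 2 Fcgr2b counts, it turned to 0.35. Flt3 was at 49.2 CPM in LT-HSC and 69.5 in CMP, but its log2 ratio turned from −0.50 to 0.085 with every cell thinned to 97978 counts and to 0.20 without CMP 1 and 2. Cd34, for which the LT-HSC gate is negative, was at 254 CPM in LT-HSC (interval 244 to 264) and 206 in CMP (interval 196 to 217), with a count in 27 of 34 LT-HSC and 24 of 24 CMP. By the mean of each cell's CPM, Cd34 was lower in LT-HSC, at 208 against 225. It differed within the gate, at 50.7 CPM in LT-HSC 1 to 16 and 361 in LT-HSC 17 to 34, and Flt3 stood at 15.2 and 67.0 CPM in these blocks.

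Sex-linked transcripts split the cells into sets that nearly matched the gates. Xist, the RNA that silences an X chromosome in female cells, had no count in any of the 34 LT-HSC or in CMP cells 1 and 2, and 7 to 226 counts in each of the other 22 CMP. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together held 1696 counts in LT-HSC, with a count in 32 of 34 cells. CMP 1 held 88 such counts and CMP 2 held 7, and the other 22 CMP held 1 between them. The gate and the sex of the donor were therefore nearly the same split, and of the CMP only 1 and 2, with 1288026 counts, matched the LT-HSC in sex-linked transcripts. No label ties these 2 cells to the animals or library pools of the LT-HSC. Values from LT-HSC against those 2 cells are given beside many of the pooled ones as within-set values, where the set means only the cells without an Xist count. Members without a count in 1 pool enter them at a floor of 3 counts. Over 10485 genes the within-set log2 ratio had a median of 0.51, and over the 10937 genes with at least 20 counts the pooled ratio had a median of −0.13.

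**Figure D1:**
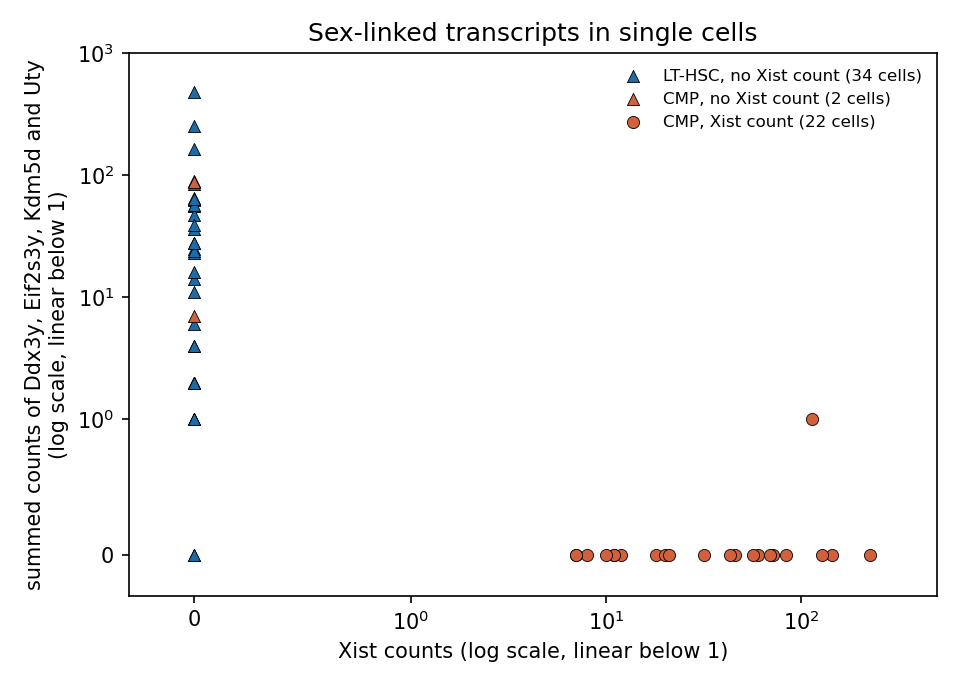
Counts of Xist (horizontal axis) and summed counts of 4 Y-linked genes (vertical axis) in each cell, both on log scales that are linear below 1. Triangles are cells without an Xist count, blue for 34 LT-HSC and orange for CMP 1 and 2, and circles are the other 22 CMP, of which 1 held a single Y-linked count.

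The LT-HSC differed by cell number, in a cut chosen after their values were seen and given by no label. Genes of the stem cell list made up 169 of 10000 counts in the median of LT-HSC 1 to 16 (range 91.7 to 281) and 66.8 in the median of LT-HSC 17 to 34 (range 16.3 to 217). Genes of the granulocyte and monocyte list made up 14.2 and 31.2, and genes of S, G2 and M phase 24.5 and 59.4. Over the whole LT-HSC pool, Ifitm1 and Ifitm3 gave 3115 and 2519 of the stem cell list's 9128 CPM, so its summed share follows these genes most. With LT-HSC 1 to 16 as the LT-HSC pool, the median log2 ratio to CMP was 3.45 for stem cell genes, −3.78 for granulocyte and monocyte genes, −0.52 for erythroid, −2.14 for S phase, −3.43 for G2 and M and 0.27 for immediate early genes. With LT-HSC 17 to 34 these medians were 1.66, −2.91, −1.99, −0.10, −0.998 and −2.27. The other pooled LT-HSC values mix both blocks.

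Genes of the stem cell list were higher in LT-HSC. Of its 36 members, 29 were at least 2-fold higher in LT-HSC, 1 was at least 2-fold higher in CMP and 6 lay between. The median log2 ratio was 2.75, above that of all 10000 random lists matched on expression (percentile 100). Procr, the endothelial protein C receptor used to isolate stem cells, stood at 119 CPM in LT-HSC and 0.85 in CMP, with a log2 ratio of 7.01 (interval 6.00 to 8.58). Sult1a1, a sulfotransferase, stood at 122 and 0.85 CPM. Of the genes of transcriptional regulators, Hlf was at 78.1 CPM in LT-HSC and 13.3 in CMP, Mecom at 24.6 and 3.96, Meis1 at 245 and 85.5, and Mllt3 at 113 and 21.1. Without CMP 1 the log2 ratio of Mllt3 moved from 2.41 to 3.07. Hlf had a count in 19 of 34 LT-HSC and 19 of 24 CMP, but at least 10 counts in 13 LT-HSC and 2 CMP. The interferon-induced membrane protein genes Ifitm1 and Ifitm3, the most abundant members, stood at 3115 and 2519 CPM in LT-HSC and at 459 and 698 in CMP. CMP 19 held 43.3% of the CMP counts of Ifitm1, and without it the log2 ratio moved from 2.76 to 3.49. Gprasp2, the member at least 2-fold higher in CMP, rested on few cells, since 1 LT-HSC held all 8 of its LT-HSC counts and 1 CMP held 44 of its 56 CMP counts. Cdkn1c had no CMP count. It was at least 17.5-fold higher in LT-HSC, but LT-HSC 5 gave 85.1% of its counts, and without that cell the bound fell to 2.63-fold. Within the set, 34 of 36 members were higher in LT-HSC and 1 was lower, with a median of 3.57.

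The 12 genes that the size rule took as highest in LT-HSC were Fcgrt, Bdh2, Nupr1, Lhcgr, Tgm2, Sult1a1, Procr, Tnip3, Plxna4os1, Col16a1, Fscn1 and Ndn. Fcgrt, the heavy chain of the neonatal Fc receptor (chromosome 7, 45092990 to 45103851, minus strand), had 439 counts in LT-HSC and none in CMP, and was at least 104-fold higher. Nupr1, a stress-induced chromatin protein gene (chromosome 7, 126623249 to 126630861, minus strand), was at 81.4 CPM in LT-HSC, with a count in 23 of 34 cells, and 0.28 in CMP, with 2 counts. Tgm2, a transglutaminase (chromosome 2, 158116402 to 158146436, minus strand), stood at 66.4 and 0.42 CPM, a log2 ratio of 7.07 (interval 5.73 to 9.57). Lhcgr, the luteinising hormone receptor (chromosome 17, 88716481 to 88791990, minus strand), was at 46.2 CPM in LT-HSC, with a count in 14 cells, and had 1 count in CMP. Without CMP 10 the log2 ratio of Nupr1 moved from 7.85 to 8.53, and without CMP 12, which held the 1 CMP count, Lhcgr was at least 105-fold higher in LT-HSC. Bdh2, Col16a1 and Fscn1 also had 1 CMP count each, and without the cell that held it were at least 109-fold, 49.2-fold and 42.5-fold higher. Tnip3, which restrains NF-kB signalling, stood at 75.4 and 0.57 CPM. Plxna4os1 is annotated antisense to another gene, and counts of the pair cannot be told apart if strand was not used. None of the 12 had a count in CMP 1 or 2. The rule took genes with few CMP counts, from 0 to 7 over all 24 CMP. Their absence from these cells is therefore no check apart from the set.

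Genes of the granulocyte and monocyte lineages were higher in CMP. Of 24 members, 16 were at least 2-fold higher in CMP, 1 in LT-HSC and 7 lay between, with a median log2 ratio of −2.17 (percentile 0). The median was −2.96 after thinning, −3.19 without the shallowest cells and −3.22 over members with at least 100 counts. Mpo, the myeloperoxidase of neutrophil granules (chromosome 11, 87793581 to 87804413, plus strand), was at 2086 CPM in CMP (interval 2053 to 2120) and 41.1 in LT-HSC (interval 37.2 to 45.3), 50.8-fold higher in CMP. All 24 CMP held at least 10 Mpo counts, and 6 of 34 LT-HSC did. LT-HSC 1 to 16 held 2 Mpo counts and LT-HSC 17 to 34 held 406. Elane, neutrophil elastase (chromosome 10, 79886247 to 79888215, plus strand), had 4481 counts in CMP and 3 in LT-HSC, a log2 ratio of −10.81 (interval −13.31 to −9.49). Ctsg, cathepsin G, stood at 1108 and 7.65 CPM, and LT-HSC 31 held 97.4% of its LT-HSC counts. Without that cell its log2 ratio moved from −7.17 to −12.09. Cst7, an inhibitor of cysteine proteases, had 1799 counts in CMP and 1 in LT-HSC, a log2 ratio of −10.72 (interval −16.61 to −8.82). Without LT-HSC 28, which held that count, Cst7 was at least 830-fold higher in CMP. Irf8, a transcription factor of the monocyte lineage, stood at 303 CPM in CMP and 12.6 in LT-HSC, and LT-HSC 18 held 89.6% of its LT-HSC counts. Without that cell its log2 ratio moved from −4.58 to −7.67. Lyz2, a lysozyme gene, was the member at least 2-fold higher in LT-HSC, at 463 CPM in LT-HSC and 171 in CMP. Within the set, 16 of 24 members were lower in LT-HSC, with a median of −1.09. Mpo there had a log2 ratio of −4.94 and Elane −8.58.

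Markers of mature neutrophils, which both gates should lack, were present at low levels in LT-HSC, 6 of the 9 in nearly all of these cells. S100a8 and S100a9 had a count in 34 of 34 LT-HSC, Camp and Lcn2 in 33, Ngp and Ltf in 32, Retnlg in 25, Mmp9 in 18 and Mmp8 in 14, with medians of 42.5 counts per cell for S100a8 and 5.5 for Camp. The 9 markers made up 3.38 of 10000 counts in the median LT-HSC (range 2.19 to 6.06) and 5.91 in the median of the 22 CMP with Xist (range 0.03 to 59.4). Over the pools, 4 of the 9 markers were at least 2-fold higher in CMP and 1 in LT-HSC, with a median log2 ratio of −0.94.

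The size rule took 12 genes as highest in CMP: Elane, Cst7, Tnfaip3, Kif13b, Tcam1, Hist1h1d, Cenpj, Hlx, Zbtb2, Slc8a1, Dis3l and Dram1. The last 10 had no count in LT-HSC. Tnfaip3, the ubiquitin-editing enzyme A20 that restrains NF-kB, was at least 112-fold higher in CMP, with a count in 22 of 24 CMP. Only 3 CMP held at least 10 counts, and after thinning Tnfaip3 had a count in 14 of 22 CMP. CMP 20 held 48.95% of its counts, and without it the bound fell to 60.6-fold. Hlx, a homeobox transcription factor gene, had 157 counts in 14 CMP and was at least 73.6-fold higher. Cenpj, a centriole assembly gene, had 158 counts in 11 CMP and was at least 74.1-fold higher, and without CMP 15 at least 47.8-fold. Hist1h1d, a linker histone gene, was at least 86.2-fold higher, and CMP 1 held 46.2% of its counts, without which the bound fell to 51.6-fold. Without the cell that moved each most, Zbtb2, Slc8a1 and Dram1 were at least 38.2-fold, 35.9-fold and 32.7-fold higher. Of these 10 genes, 6 had a count in CMP 1 or 2, and Tnfaip3, Kif13b, Zbtb2 and Slc8a1 had none. By the share of the other 22 CMP with a count of each gene, 3.08 of the 10 would be absent from 2 cells, near the 4 seen. That number does not allow for CMP 1 and 2 being the deepest CMP.

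**Figure D2:**
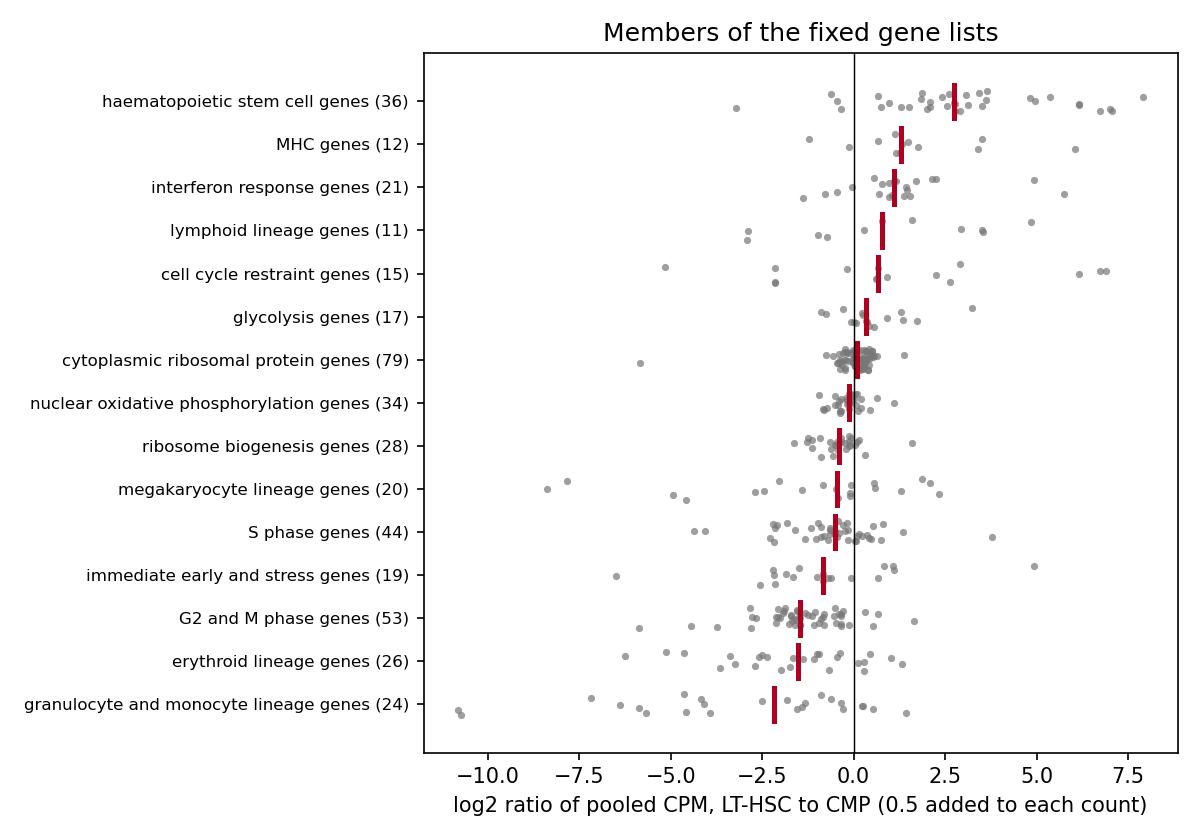
Log2 ratio of pooled CPM, LT-HSC to CMP, for each member with at least 20 counts of the 15 fixed gene lists (grey points), with the list's median as a red bar and its number of members in brackets. The median was 2.75 for the stem cell genes and −2.17 for the granulocyte and monocyte genes.

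Erythroid lineage genes were also higher in CMP in most cases. Of 26 members, 16 were at least 2-fold higher in CMP, 2 in LT-HSC and 8 lay between, with a median log2 ratio of −1.52 (percentile 0). Gata1, the erythroid and megakaryocytic master regulator (chromosome X, 7959260 to 7978071, minus strand), stood at 65.8 CPM in CMP and 2.62 in LT-HSC, a log2 ratio of −4.63 (interval −5.28 to −4.08). Mfsd2b, a sphingolipid transporter, stood at 65.1 and 0.81 CPM, with a log2 ratio that moved from −6.25 to −6.84 without LT-HSC 1, and Car1, a carbonic anhydrase, at 441 and 73.1. Klf1 differed less, at 83.1 CPM in CMP and 32.0 in LT-HSC. LT-HSC 33 held 62.9% of the LT-HSC counts of Klf1, and without it the log2 ratio moved from −1.38 to −2.68. Car2, another carbonic anhydrase, was higher in LT-HSC, at 1646 against 659 CPM, and Hemgn stood at 41.5 and 20.2. Car2 was the most abundant member, and the summed level of the list was close in both pools, at 2447 CPM in LT-HSC and 2462 in CMP. Within the set the list's median was −1.49.

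Megakaryocyte genes went both ways. Of 20 members, 8 were at least 2-fold higher in CMP, 4 in LT-HSC and 8 lay between, with a median of −0.46 (percentile 18.6). With LT-HSC 1 to 16 only the median was −0.45, and with LT-HSC 17 to 34 only −1.71. Pf4, platelet factor 4, was at 1002 CPM in CMP and 41.9 in LT-HSC, but 45.1% of its CMP counts came from 1 CMP and 59.9% of its LT-HSC counts from LT-HSC 30. Without LT-HSC 30 the log2 ratio moved from −4.58 to −5.85. Pf4 had no count in CMP 1 and 2, so that within the set it was higher in LT-HSC. Vwf, the von Willebrand factor gene, stood at 37.3 CPM in LT-HSC and 15.3 in CMP, and without LT-HSC 4 its log2 ratio moved from 1.28 to 0.44. Within the set the list's median was 1.91, with 16 of 19 members higher in LT-HSC. The lymphoid list had 11 members with enough counts and a median of 0.78 (percentile 95), and no direction was drawn. The median was −1.71 over all members with a count, 0.27 over those with at least 100 counts and −0.37 with LT-HSC 1 to 16 only, and within the set it was 0.43. Of the 11, 5 were at least 2-fold higher in LT-HSC and 2 in CMP. Gata3 stood at 22.6 CPM in LT-HSC and 0.71 in CMP, and Dntt at 5.54 and 41.8. Without CMP 1 the log2 ratio of Dntt moved from −2.90 to −1.85. Vpreb1 rested on LT-HSC 3 alone, and its log2 ratio of 3.55 moved to −3.28 without that cell, when LT-HSC held no count and CMP 3.

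Cell cycle genes were higher in CMP. For the 53 genes of G2 and M phase the median log2 ratio was −1.48 (percentile 0), with 34 members at least 2-fold higher in CMP and 1 in LT-HSC. Without LT-HSC 17 it was −1.92, and with every cell thinned to 97978 counts −2.17. Mki67, a marker of cycling cells, stood at 229 CPM in CMP and 60.0 in LT-HSC, Top2a, a topoisomerase, at 259 and 62.3, and Kif11, a spindle motor, at 92.46 and 12.99. At least 10 Mki67 counts were held by 18 of 24 CMP and 2 of 34 LT-HSC, and of the LT-HSC counts 12 were in LT-HSC 1 to 16 and 584 in LT-HSC 17 to 34. Without LT-HSC 33 the log2 ratio of Mki67 moved from −1.93 to −2.82. For Kif11, LT-HSC 17 held 63.6% of the LT-HSC counts, and without it the log2 ratio moved from −2.83 to −4.16. The 44 genes of S phase differed less, with a median of −0.51 (percentile 0.96), 12 members at least 2-fold higher in CMP and 2 in LT-HSC. By the mean of each cell's CPM that median was −1.03. Mcm4 stood at 145 CPM in CMP and 33.9 in LT-HSC, and Blm, a DNA helicase, at 89.9 and 4.33. Without LT-HSC 18 the log2 ratio of Blm moved from −4.36 to −5.25. Within the set the G2 and M median was −0.60, and the S phase median was −0.06. Counts of both lists together made up 29.3 of 10000 in the median LT-HSC (range 14.7 to 208) and 126 in the median CMP (range 70.6 to 234). In CMP 1 they made up 157 and in CMP 2 71.3.

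Genes that restrain the cell cycle had a median of 0.67 over 15 members (percentile 94.1), with 6 at least 2-fold higher in LT-HSC and 4 in CMP. Txnip stood at 421 CPM in LT-HSC and 56.4 in CMP, and Ndn, which encodes necdin, at 25.3 and 0.28. Without CMP 5 the log2 ratio of Ndn moved from 6.16 to 6.83. Btg2 and Cdkn1a, the gene of p21, went the other way, at 27.4 against 122 CPM and 15.8 against 69.9. Their log2 ratios moved from −2.16 to −2.98 without LT-HSC 12 and from −2.14 to −2.80 without LT-HSC 17. Within the set the median was 1.88. Immediate early and stress genes had a median of −0.85 over 19 members (percentile 0.85), with 8 at least 2-fold higher in CMP and 3 in LT-HSC, but with LT-HSC 1 to 16 only the median turned to 0.27. Jun stood at 289 CPM in CMP and 64.1 in LT-HSC, Fos at 855 and 428, and Fosb at 151 and 25.3. The list did not keep its direction within the set either. Its median there was 2.29, and 17 of 18 members were higher in LT-HSC. The list summed to 1579 CPM in LT-HSC, 327 in CMP 1 and 2 and 3355 in the other 22 CMP.

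Genes of growth and metabolism differed little. Ribosomal protein genes had a median of 0.09 over 79 members (percentile 93.5), and 77 of them lay within 2-fold. Within the set that median was −0.17, so no direction was drawn. Ribosome biogenesis genes had a median of −0.40 (percentile 2.49). Of the 28, 22 lay within 2-fold, 5 were higher in CMP and 1 in LT-HSC. Nolc1, a nucleolar chaperone, stood at 183 CPM in CMP and 75.8 in LT-HSC, and Ncl, nucleolin, at 930 and 503. Nuclear genes of oxidative phosphorylation had a median of −0.14, close to that of all genes, and 33 of 34 lay within 2-fold. Glycolysis genes had a median of 0.35 (percentile 97.1), with 13 of 17 within 2-fold and 4 higher in LT-HSC. Pkm stood at 826 CPM in LT-HSC and 340 in CMP. Ldhb stood at 142 and 15.1, and without CMP 12 its log2 ratio moved from 3.23 to 3.95. Within the set the glycolysis median was 1.01. No mitochondrially encoded gene was listed in the table.

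Interferon response and MHC genes were higher in LT-HSC. Of 21 interferon response genes, 12 were at least 2-fold higher in LT-HSC and 1 in CMP, with a median of 1.09 (percentile 99.99). Xaf1 stood at 78.5 CPM in LT-HSC and 17.7 in CMP, and Gbp2, a guanylate-binding protein, at 76.4 and 23.2. Ifi27l2a was the member at least 2-fold higher in CMP, at 62.4 against 24.1, and without LT-HSC 23 its log2 ratio moved from −1.37 to −2.32. Isg15 rested on few cells. It had a count in 5 LT-HSC and 4 CMP, and without CMP 1 its log2 ratio moved from 2.24 to 5.21. Of 12 MHC genes, 9 were at least 2-fold higher in LT-HSC and 1 in CMP, with a median of 1.29 (percentile 100). The class I genes H2-K1 and H2-D1 stood at 2225 and 1869 CPM in LT-HSC and at 890 and 841 in CMP, and B2m, the shared light chain, at 10627 and 4867. H2-D1 and H2-K1 belong to a family of close copies, between which counting may have split reads. Of the class II genes, H2-Ab1 stood at 114 and 33.6, while H2-DMa was close in both pools, at 203 and 224. Without LT-HSC 34 the log2 ratio of H2-Ab1 moved from 1.77 to 1.12, and with LT-HSC 1 to 16 only it turned to −0.44. Within the set the interferon median was 1.197, with 15 of 21 members higher in LT-HSC and 6 lower. There it stood at percentile 76.1 of random lists, so the interferon list did not stand apart from other genes within the set. The MHC median within the set was 1.62 (percentile 97.9).

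Markers of other cell types were also compared between the pools. Whether their transcripts came from other cells or from the gated cells themselves was not tested. All 6 measured markers of basophils, mast cells or eosinophils were at least 2-fold higher in CMP. Within the set this rested on Cpa3, since CMP 1 and 2 held 1 count of Mcpt8 between them and none of Prg2, Prss34, Fcer1a or Ms4a2. Cpa3, a mast cell protease gene, stood at 249 CPM in CMP and 10.3 in LT-HSC, and had a count in 23 of 24 CMP, at least 10 in 8 of them. CMP 1 held 116 Cpa3 counts and CMP 2 held 2. Another CMP held 783, without which the CMP level was 143 CPM, and LT-HSC 23 held 78.4% of the LT-HSC counts, without which the log2 ratio moved from −4.60 to −6.75. Mcpt8, a basophil protease gene, stood at 55.9 CPM in CMP, where 1 cell held 159 of its 395 counts, and had 14 counts in LT-HSC, all in LT-HSC 31. Without LT-HSC 31 it was at least 183-fold higher in CMP. Prss34 had 166 counts in 17 CMP and none in LT-HSC, but 1 cell held 116 of them and 2 CMP held at least 10. Without the cell that moved each most, Prss34, Ms4a2 and Fcer1a were at least 23.8-fold, 12.5-fold and 2.38-fold higher in CMP. The 2 measured endothelial markers had a median of 2.46, with Emcn at 42.2 CPM in LT-HSC and 12.2 in CMP. Without CMP 5 the log2 ratio of Emcn moved from 1.79 to 2.47. The dendritic cell set rested on Ly6d, at 0.81 and 7.65 CPM, and the stromal set on Col1a2, at 13.4 and 5.95 CPM, each count of which came from 1 cell per pool. No marker of B cells, T or NK cells, or macrophages reached 20 counts, but only 3 of 6 B cell and 7 of 9 T or NK markers were among the listed symbols.

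CMP had more detected genes per cell than LT-HSC. The median was 6856 genes (range 5220 to 8440) against 4147 (range 2266 to 5839). With every cell thinned to 97978 counts, which left out 4 LT-HSC and 2 CMP, the medians were 5509 (range 3688 to 6435) and 3296 (range 2457 to 4006). At this depth CMP 1 had 5529 genes and CMP 2 3688. Counting only genes with at least 10 counts, the thinned medians were closer, at 1936 and 1730.

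**Figure D3:**
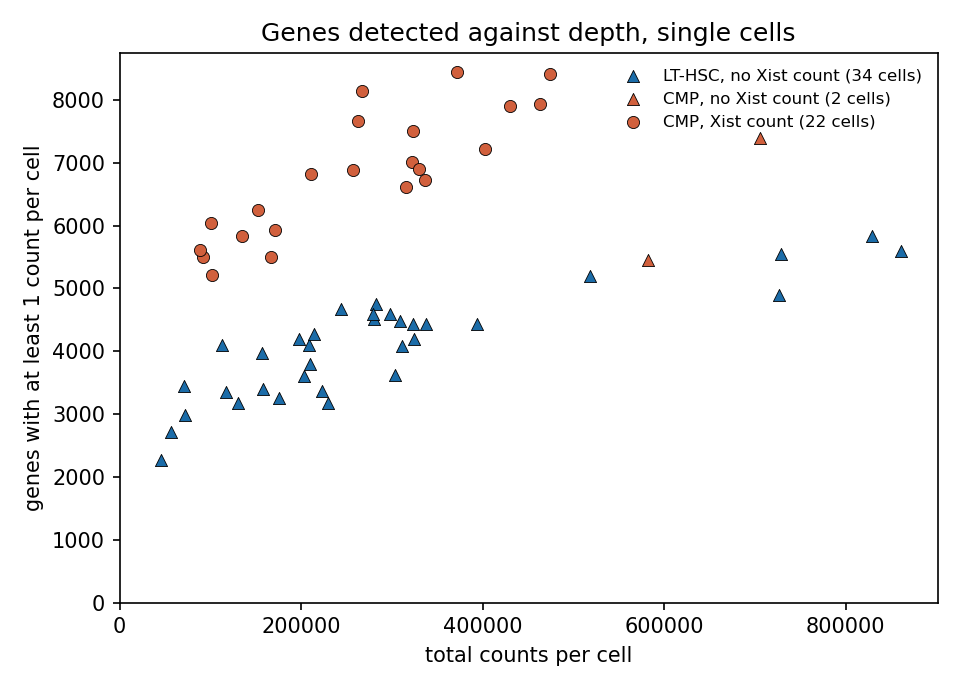
Number of genes with at least 1 count (vertical axis) against total counts (horizontal axis) for each of the 58 cells. Blue triangles are LT-HSC, orange triangles are CMP 1 and 2, and orange circles are the other 22 CMP. The range was 2266 to 5839 genes in LT-HSC and 5220 to 8440 in CMP.

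Single CMP held transcripts of both the granulocyte-monocyte and the erythroid lineage. Counts of Mpo or Elane together with counts of Gata1 or Klf1 were found in 22 of 24 CMP (91.7%, exact Clopper-Pearson interval 73.0% to 98.97%). In the other 2 CMP only Mpo or Elane had counts. With at least 10 counts of each, 13 of 24 CMP (54.2%) held both, and after thinning 17 of 22 (77.3%) did. In LT-HSC, 12 of 34 held both by at least 1 count, 2 by at least 2 counts, and none by at least 10 or after thinning. The exact interval of 0 of 34 reaches up to 10.3%, and that of 0 of 30 after thinning up to 11.6%. Across the erythroid list, a CMP had counts for a median of 23.5 members, and an LT-HSC for 13.5.

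The content of stem cell genes varied widely within the LT-HSC gate. Stem cell genes made up 117 of 10000 counts in the median LT-HSC, from 16.3 to 281, and 19.8 in the median CMP, from 4.86 to 43.0. Ifitm1 and Ifitm3, the most abundant members, weigh most in this sum over the pools. Genes of the granulocyte and monocyte list made up 19.96 in the median LT-HSC, from 6.37 to 56.5, and 119 in the median CMP, from 10.9 to 254. CMP 1 and 2 had 9.98 and 8.70 of stem cell genes, below each LT-HSC, and 45.9 and 128 of granulocyte and monocyte genes. Ward clustering on 1000 variable genes did not part the gates at 2 clusters. It set the shallowest LT-HSC, with 45022 counts, apart from the other 57 cells. At 4 clusters, 23 LT-HSC formed cluster 2, 9 LT-HSC and all 24 CMP formed cluster 1, and the last 2 clusters were single LT-HSC. All of LT-HSC 1 to 16 lay in cluster 2, and the 9 LT-HSC of cluster 1 were all from LT-HSC 17 to 34. Cluster 1 was led by Ctsg, Elane and Mpo, and cluster 2 by Gkn3, Sult1a1 and Slfn2, though LT-HSC 10 held 98.2% of the Gkn3 counts. In cluster 1, Ctsg and Elane rested almost only on the CMP. LT-HSC 17 to 34 held no Elane count, and LT-HSC 31 held 97.4% of the LT-HSC counts of Ctsg. Mpo had 406 counts in LT-HSC 17 to 34.

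**Figure D4:**
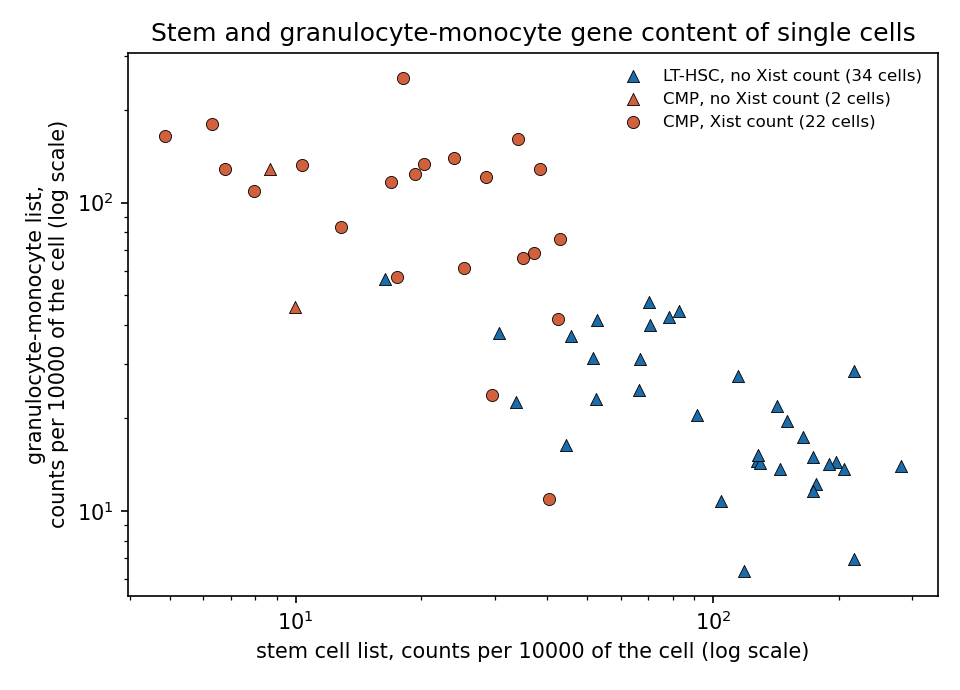
Counts of the stem cell list (horizontal axis) and of the granulocyte and monocyte list (vertical axis) per 10000 counts of each cell, both on log scales. Blue triangles are LT-HSC, orange triangles are CMP 1 and 2, and orange circles are the other CMP. LT-HSC ranged from 16.3 to 281 on the horizontal axis and CMP from 4.86 to 43.0.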

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

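No paired analysis was possible because the numbers in the labels only name cells and no result comes from a test. Alternatives that use only cells without Xist, leave out CMP 1 and 2, take LT-HSC 1 to 16 or 17 to 34 only, ask for 10 counts, or cluster unscaled genes or without shallow cells were chosen after seeing the data. All 15 list medians stayed within the 95% binomial interval of the median over their members when CMP 1 and 2 or shallow cells were left out, with an added count of 1, with a total without ribosomal protein genes and with other member minimums. These intervals are wide, and large shifts lie inside them. The lymphoid median changed sign, to −1.71, over members with at least 1 count, and was 0.27 over those with at least 100. The granulocyte and monocyte median moved from −2.17 to −3.19 without shallow cells and to −3.22 over members with at least 100 counts. By the mean of each cell's CPM the S phase median moved to −1.03 and the G2 and M median to −2.13. After thinning they moved to −0.88 and −2.17. When single cells were left out, the medians with the widest ranges were those of lymphoid genes, from 0.24 to 1.11, granulocyte and monocyte genes, from −2.70 to −2.06, megakaryocyte genes, from −0.74 to −0.13, and G2 and M genes, from −1.92 to −1.31. Median-of-ratios scaling moved the median of all genes from −0.13 to −0.01 and that of oxidative phosphorylation to −0.018. With only cells without Xist, in which the median of all genes was 0.70, the medians of stem cell, megakaryocyte, cell cycle restraint, immediate early and glycolysis genes moved to 5.64, 4.13, 3.45, 2.92 and 1.01. S phase moved to −0.061, G2 and M to −0.68, and ribosomal protein genes reversed to −0.17. The CMP pool there held 2 cells, in which 24 of the 36 stem cell genes had no count, so such medians depend on the added count. With LT-HSC 1 to 16 only, the medians of S phase, G2 and M, ribosome biogenesis, ribosomal protein, oxidative phosphorylation and interferon response genes moved to −2.14, −3.43, −0.65, 0.27, −0.42 and 1.56, and the lymphoid and immediate early medians changed sign, to −0.37 and 0.265. With LT-HSC 17 to 34 only, stem cell, S phase and immediate early genes moved to 1.66, −0.10 and −2.27, and ribosomal protein genes reversed to −0.030.

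Of 1079 alternative values for 91 named genes, 1061 kept their direction. Most of these genes were chosen for large log2 ratios, and an added count of 1 left all 91 within their intervals. The number that kept their direction was therefore largely fixed in advance. With only cells without Xist, Gp1bb reversed to 2.26, Pf4 to 6.76, Fosb to 1.17, Jund to 0.65, Ndufs1 to 0.16, Isg15 to −0.066, Fcgr2b to 0.35 and Ddx3y to −0.21. Gp1bb and Pf4 had no count in CMP 1 and 2, so the size of these values rests on the added count. Against a floor of 3 counts, Pf4 stays higher in LT-HSC but Gp1bb does not. LT-HSC 10 held 17 of the 18 LT-HSC counts of Gp1bb. Flt3 reversed to 0.085 after thinning and 0.20 without CMP 1 and 2, Cd34 to −0.12 by the mean of each cell's CPM, and Vpreb1, which ran from −3.28 to 3.98 when single cells were left out, to the lower value without LT-HSC 3. With LT-HSC 1 to 16 only, Cd34 reversed to −2.02, Ccne2 to −2.41, Slc2a3 to −0.29, Pdk1 to −0.35 and H2-Ab1 to −0.44, and with LT-HSC 17 to 34 only Vpreb1 reversed to −2.69. Median genes per LT-HSC moved to 3296 after thinning, 2912.5 at 2 counts and 2044 at 10, and per CMP to 5509, 5124 and 2982.5. CMP with both lineages moved to 54.2% at 10 counts. In 7 of 9 clustering settings both gates shared their main cluster, with 51 to 57 cells in it. After thinning (40 of 52 cells) and without scaling genes (43 of 58), the main clusters differed, with 12 and 15 LT-HSC in the cluster of the CMP. The cause of these changes was not tested. Depth limits genes with few counts most, since a gene absent from a pool is bounded only at 0.30 CPM in LT-HSC and 0.42 in CMP.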

Other observations

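3 genes with most of their counts in few CMP, Tnf, Nlrp3 and Tnfaip3, were chosen after their values were seen, with no list or test behind the choice. Tnf had 470 counts, of which 1 cell held 334, and it had a count in 9 CMP. Nlrp3, an inflammasome sensor gene, had 116 counts in 14 CMP, of which 1 cell held 60. Tnfaip3 had 239 counts in 22 CMP, of which 1 cell held 117. None of the 3 had a count in LT-HSC or in CMP 1 and 2. LT-HSC 25, the shallowest cell, was led by Wfdc17 at 6197 CPM, by H2-Aa at 3198 and by H2-Eb1 at 1533, against 10.9, 22.7 and 10.1 CPM in the mean of the other 57 cells. Of the LT-HSC pool's H2-Eb1 counts, 63.1% came from LT-HSC 27.

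The tests of genes per cell and of the mix of neutrophil markers below were chosen after the results were seen, and the tests of set-dependent genes, of the summed neutrophil share and of whole neutrophils were written before. CMP had more genes per cell than LT-HSC. Depth in deposited counts did not account for the excess of genes with at least 1 count, since at 1 depth the ratio of medians was still 1.67. If the counts are reads, thinning does not even out the molecules captured per cell, and a difference in these was not tested. Counting only genes with at least 10 counts, the medians at that depth were closer, at 1936 in CMP and 1730 in LT-HSC. A donor or library set could account for part of the excess, if CMP 1 and 2 share one with the LT-HSC, which no label gives. Of the CMP without Xist, 1 of 2 lay inside the LT-HSC range of 2457 to 4006 genes at that depth and the other lay above it, so the set and the gate cannot be told apart with 2 cells. A difference between the gates themselves stays open and untested apart from the set.

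Some genes separated nearly all CMP with Xist from nearly all LT-HSC. There were 9 with a count in at least 20 of these 22 CMP and at most 3 LT-HSC: Arhgap11a, Cd69, Cst7, Ctsg, Elane, Mcpt8, Sik1, Tnfaip3 and Urb2. If they marked a donor or library set that CMP 1 and 2 share with the LT-HSC, they should have been absent from these 2 cells. Of the 9, 6 had a count in both cells, 2 in 1 and 1 in neither, so that 11.1% were absent. This is above the bound of 10% set beforehand for setting the explanation aside. With 9 genes, 1 absence alone exceeds that bound. That test counts a gene with a single count as present. Mcpt8 and Sik1 had 1 count each in CMP 1 and 2 together, where their level in the other CMP would give 87.9 and 40.4 by depth, and Tnfaip3 had none where 53.3 would be due. For these 3 genes the gate and the set cannot be told apart, because the set holds 2 CMP and single cells gave many of the counts (159 of 394, 63 of 181 and 117 of 239 in the CMP with Xist). Ctsg, with 96 and 80 counts in CMP 1 and 2, and Elane, with 70 and 103, were present in both cells, but below the 1706 and 961 due by depth. The other 4 were at or nearer to that level over both cells, but for Arhgap11a, Urb2 and Cd69 1 of the 2 cells held nearly all the counts. Of the 4, only Cst7 had more than a few counts in each cell. With 2 cells, which no label places in the set of the LT-HSC, this does not decide about the set. Arhgap11a had 84 and 2 counts where 83.6 would be due over both cells, Urb2 52 and 1 where 35.7 would, Cst7 176 and 51 where 351 would, and Cd69 1 and 153 where 229 would. Whether any of the 9 follows the gate itself was not tested apart from the set.

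Neutrophil granule transcripts in LT-HSC, led by S100a8 at 155 CPM, may come from free RNA of mature neutrophils in the sorted suspension, as a hypothesis. Their even summed share prompted this explanation, and a comparison of its spread with random lists was dropped because it only restated the pattern. The test written beforehand separated nothing, since 100% of LT-HSC lay within 4-fold of the median share for these markers, but also 100% for the granulocyte and monocyte list and 97.1% for the stem cell list. The mix of the 9 markers was then tested, since 1 source should keep them in 1 ratio from cell to cell. Their Pearson dispersion between cells, which is near 1 when only counting noise is present, was 0.84 in LT-HSC 1 to 16 and 1.13 in LT-HSC 17 to 34. Random lists matched on counts had medians of 24.5 and 41.2 and lowest values of 9.82 and 17.1. This is what 1 common source within each block could give. It does not say whether the source lay in the suspension or in a library pool. Expression by the stem cells in a fixed ratio was not excluded. The mix differed between the blocks. S100a8 made up 54.9% of the marker counts in LT-HSC 1 to 16 and 42.1% in LT-HSC 17 to 34. Ngp made up 6.77% and 13.6%, while S100a9 was close, at 21.4% and 20.4%. Whole neutrophils did not account for the counts, since the highest LT-HSC held 1.79 times the share of the median one. In the 22 CMP with Xist the share was not even and ran from 0.03 to 59.4 of 10000 counts, against 1.86 and 3.29 in the CMP without Xist.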
